A study of Mus musculus with 2 samples.

How the data were processed

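H3K9ac, acetylation of lysine 9 on histone H3 and a mark of active promoters and enhancers, was measured by chromatin immunoprecipitation and sequencing (ChIP-seq) in mouse embryonic facial prominence at 12.5 days after fertilisation. Both samples belong to 1 group. Per the labels, replicate 1 was pooled from 120 embryos and replicate 2 from 88 embryos of both sexes, and the size range of the DNA was 300 to 500 bp in both. The facial prominences are the swellings of the embryonic head that fuse into the face. Replicates are separate pools of tissue, so their difference holds both biological and technical spread, and 2 samples allow no test across samples.

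The authors deposited peak lists on the mouse build mm10, called against control alignments, per the file headers and the accompanying notes. The peak caller, the aligner and their versions are not given in the sources used here. There were 4 lists: 1 called on each replicate alone, 1 called on both replicates pooled, and 1 of replicated peaks, which the notes describe as derived from the pooled list and the lists of both replicates. For each peak the authors gave a score, which was not used, a fold over control (a ratio), a −log10 p-value and a −log10 q-value, and the offset of the summit from the start of the peak. The deposited fold and −log10 q are the authors' own values of each peak. They were used only to describe, rank and filter peaks within a list. A peak list holds no reads, so the depth of each library is unknown, and no counting interval or floor was computed. Deeper libraries give longer lists, so a gene with a peak in 1 list alone can differ from the other list in depth alone.

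All coordinates are mm10, 1-based. Sequence came from the GRCm38 primary assembly, which is mm10, and every peak ended within its chromosome length there. Genes came from GENCODE release M21, basic set. There were 21911 protein-coding symbols, each with the transcription start sites (TSSs) of all its basic transcripts, a median of 2 per gene. A gene was called marked when a peak overlapped 1000 bp to either side of any of its TSSs. Analyses by gene and by location used chromosomes 1 to 19, X and Y. Width was the number of bases covered by peaks within 5000 bp of a TSS, at the TSS of the gene with the most. A domain was a run of peaks merged within 1000 bp. Distal peaks lay over 2500 bp from every TSS of any annotated gene, and were counted within 100000 bp of the TSSs of a gene. Peaks were assigned to a class in the order TSS, exon, intron, intergenic, the last 3 by the summit.

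Replicate lists were compared by overlap of at least 0.5 of either peak, with chance measured by 100 random circular shifts of 1 list along each chromosome. Before the data were examined, 20 gene lists were fixed: transcription factors of facial mesenchyme, oral and facial epithelium, facial signalling, orofacial cleft genes, cartilage and bone, skeletal muscle, neurons, neural crest glia and melanocytes, forebrain and eye, endothelium, erythroid cells, macrophages, Hox genes, hepatocytes, heart muscle, pancreas and intestine, germ cells, pluripotency, ribosomal proteins and olfactory receptors. Of the symbols named in them, 99.8% matched the annotation, older names through a synonym table, and 1 did not. The share of marked members was compared with all other protein-coding genes by two-sided Fisher's exact test. It was also compared with 10000 random lists of the same size matched on promoter CpG content (observed over expected CpG within 500 bp of the most upstream TSS, in 10 bins). Gene families were compared in both ways. Width used the same matched lists, and distal peaks used lists matched on gene density in 10 bins. Permutation p-values were two-sided, and the smallest that 10000 lists can give is 0.0002. The p-values of gene lists were adjusted by the Benjamini-Hochberg method over the 20 lists, those of motifs over the 9 motifs and those of gene families over 252 families, with a threshold of 0.05. The p-values for chromosome X and for Hox genes marked in a single replicate were not adjusted. Motif sites on either strand were counted in 250 bp to either side of the summits of distal peaks and in same-sized windows 5000 bp to each side that met no peak of any list, and the counts were compared by two-sided Fisher's exact test. Genes and peaks are not replicates, so these tests describe these libraries. The random lists were drawn gene by gene over the genome. Hox genes, olfactory receptors and clustered protocadherins lie side by side and can share peaks. Tests of these lists treat linked genes as separate, so their p-values may be too small. Members of other lists can also lie near each other, and the same limit holds there.

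Genes named in the text follow a rule fixed before the data were examined: the 20 protein-coding genes with the widest domain at a TSS, in each list the 3 marked members with most bases covered and up to 3 unmarked members in alphabetical order, and the 10 protein-coding genes with the most distal peaks. The few genes outside this rule are named as chosen after their values were seen, and so were the gene families given at the end.

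The functions were tested on simulated data. All 7 interval functions matched a base-by-base count in 50 simulated sets. In 20 simulations over the 21911 genes, with marks drawn from the marked share of each CpG bin, 5 lists changed and 2000 random lists, Fisher's test found 100% of the changed lists but also called 41.2% of the unchanged ones, because CpG content differs between lists. The matched lists found 80% of the changed lists and called 0% of the unchanged ones. Both tests are therefore given, and a difference that holds only in Fisher's test is said to be so. The width test found 100% of the changed lists and called 1.15% of the unchanged ones, and the distal test 100% and 0.385%. In these simulations values were drawn or shuffled gene by gene within the bins that the matched tests use. The low rates for unchanged lists therefore follow from the setup, and do not show how the tests behave on lists of linked genes. Changes smaller than those planted were not tried. The motif search found 100% of planted TFAP2, SOX and CTCF sites in 2000 sequences each.

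Alternatives fixed before the data were examined were other overlap rules, each replicate's own list and the pooled list in place of the replicated list, a −log10 q of at least 5, TSS windows of 500 and 2500 bp, only the most upstream TSS, other windows for width and distal peaks, unmatched or GC-matched controls, and other merging distances. The comprehensive GENCODE set, genes with no other gene's TSS within 2000 bp, and random lists matched on the number of CpGs were chosen after the data were seen. Calculations used Python 3.11.15, numpy 2.4.6 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9.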

Results

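The series measured H3K9ac in 2 pools of mouse embryonic facial prominence at 12.5 days, replicate 1 from 120 embryos and replicate 2 from 88. It has 1 group, so the design gives the comparison of the replicates with each other and a description of where the mark lay. The list of replicate 1 held 68289 peaks over 29.4 Mb and that of replicate 2 held 76298 peaks over 35.7 Mb. The pooled list held 76529 peaks over 39.4 Mb, and the replicated list held 29543 peaks over 28.5 Mb. Median peak width was 236 bp in replicate 1, 245 bp in replicate 2, 264 bp in the pooled list and 712 bp in the replicated list. The median of the authors' fold was 3.40, 3.08, 2.90 and 4.97 in the same order. The lowest −log10 q was 0.299, 0.240, 0.351 and 0.378, and 25.5%, 25.4%, 30.3% and 74.8% of the peaks reached at least 5. All lists therefore hold weak calls, and a peak in a list is not by itself a significant one. The number of reads is unknown, so the lengths of the lists are not a measure of how much of the mark each pool held.

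The strongest peaks were shared by the replicates and the weak ones mostly were not. Of the 10000 peaks with the highest fold, 99.8% of those of replicate 1 were met by a peak of replicate 2, and 99.97% of those of replicate 2 by a peak of replicate 1. Over the whole lists the shares were 41.7% and 33.3%. Shifted lists gave a mean of 2.02% and 1.79%, and at most 2.33% and 2.09% in 100 shifts. The replicates shared 0.418 of the bases covered by either, against 0.00685 in shifted lists. Peaks with a −log10 q of at least 5 were met in 94.6% of cases in replicate 1 and 91.6% in replicate 2, and the other peaks in 23.6% and 13.4%. Where both lists were restricted to a −log10 q of at least 5, 89.4% and 75.5% were met. Across 25384 replicated peaks on chromosomes 1 to 19, X and Y that met both lists by at least 1 bp, the folds of the replicates had a Spearman correlation of 0.849, which is across peaks that are not independent replicates. Median fold in these was 5.22 in replicate 1 and 5.87 in replicate 2.

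**Figure D1:**
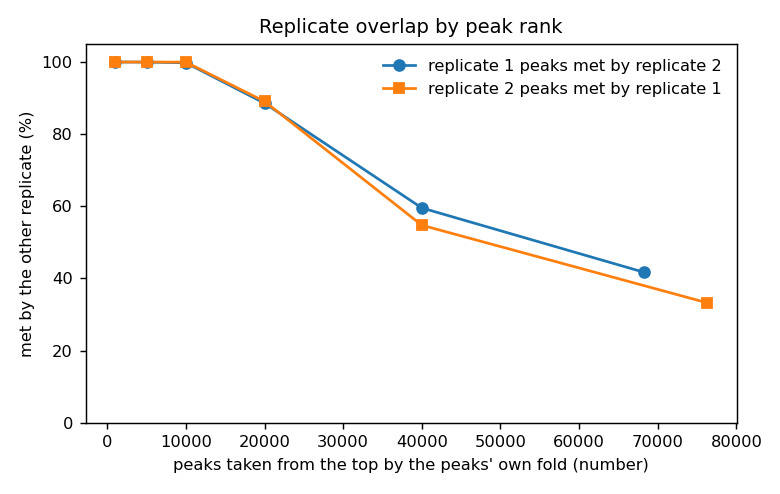
Share of peaks met by the other replicate (y axis, percent) against the number of peaks taken from the top by the peaks' own fold (x axis), with 1 line per replicate. The share is 88.6% for the first 20000 peaks of replicate 1 and 89.1% for those of replicate 2, and falls to 41.7% and 33.3% over the whole lists.

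The replicated list was a part of the pooled list. All 29543 replicated peaks had the coordinates and the q of a pooled peak, and 25255 of them, or 85.5%, were met by a peak of both replicates. A further 1196 were met by replicate 1 only, 2975 by replicate 2 only and 117 by neither, under the rule of 0.5 of either peak. All 25255 pooled peaks met by both replicates were in the replicated list. The 46986 pooled peaks left out had a median width of 209 bp and a median fold of 2.64, against 712 bp and 4.97 for the replicated ones.

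The mark lay mostly at the starts of genes. Of the replicated peaks on chromosomes 1 to 19, X and Y, 18161, or 61.5%, lay within 1000 bp of a TSS. This class holds 4.37% of the genome, so the ratio was 14.1. A peak counted there when any part of it came within reach, while the genome share counts single bases, so peak width raises this ratio. The other classes went by the summit, so their shares do not compare directly with it. Introns held 21.2% of the peaks against 40.3% of the genome, exons away from TSSs 5.16% against 2.91%, and intergenic sequence 12.2% against 52.4%. In replicates 1 and 2, introns held 37.0% and 39.7% of the peaks, near their share of the genome, and intergenic sequence held 21.3% in each. Peaks at TSSs had a median width of 1062 bp and a median fold of 8.11, and those in introns 401 bp and 3.34. In replicates 1 and 2 the median widths were 556 and 663 bp at TSSs, and 203 and 212 bp in introns. The median folds there were 5.37 and 5.60 at TSSs, and 3.15 and 2.84 in introns. Within the lists of single replicates, 35.7% of the peaks of replicate 1 and 32.5% of those of replicate 2 lay at TSSs. In bases, TSS peaks made up 79.1% of the replicated list, 62.6% of replicate 1 and 61.1% of replicate 2.

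A TSS peak was found for 13768 of 21911 protein-coding symbols, or 62.8%, in the replicated list. The list of replicate 1 marked 14103 and that of replicate 2 marked 14503, with 13707 genes in both, 396 in replicate 1 only and 796 in replicate 2 only. Antisense genes were marked in 32.9% of cases, lincRNA genes in 13.1% and processed pseudogenes in 1.29%, the last in 2.42% in replicate 1 and 3.15% in replicate 2. The share followed promoter CpG content: 3.28% of the coding genes in the lowest CpG decile were marked, 39.7% in the fourth and 98.7% in the highest. Replicate 1 gave 4.93% and 98.7% in the lowest and the highest decile, and replicate 2 gave 5.52% and 99.1%. Gene lists were therefore also set against random lists matched on promoter CpG.

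All 35 transcription factors of facial mesenchyme carried a replicated TSS peak, as they did in the list of each replicate. The list includes Six2, Lhx8, Satb2, Twist1 and Msx1, which pattern and maintain the mesenchyme of the face and palate. The adjusted p was 4.9e-07 by Fisher's exact test. Random lists matched on CpG had a median of 31 marked genes of 35, with an adjusted permutation p of 0.0047. All 30 orofacial cleft genes were marked, against a matched median of 26 (adjusted p = 3.8e-06 by Fisher's exact test and 0.001 by permutation), with 28 in replicate 1 and 30 in replicate 2. Some of its members, such as Satb2, Pax9 and Msx1, are also in the list of mesenchymal factors. Others, such as Ptch1, are also in the facial signalling list, so the results of these lists are not independent of each other. Facial signalling genes were marked in 26 of 27 cases, among them Wnt5a, Pdgfra and Ptch1. The unmarked member was Shh, which encodes the ligand of the Hedgehog pathway, and it had a TSS peak in replicate 2 but not in replicate 1. The adjusted p of the signalling list was 0.000178 by Fisher's exact test, but it did not pass the test against matched lists (adjusted p = 0.270 by permutation).

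Markers of several other tissues were marked less often than other genes. Of 26 hepatocyte genes only Foxa3 had a replicated TSS peak, and of 22 germ cell genes only Dazl, a germ cell RNA-binding protein. The lists of single replicates marked more of them, with 3 hepatocyte genes in each, and 5 germ cell genes in replicate 1 and 3 in replicate 2. Hepatocyte genes lay below matched lists (median 6, adjusted p = 0.017 by permutation), as did germ cell genes (median 12, adjusted p = 0.001) and the 4 of 20 marked pancreas and intestine genes (median 9, adjusted p = 0.0047), of which replicate 1 marked 5 and replicate 2 marked 8. Alb, Afp and Ahsg, secreted liver proteins, had no replicated or single-replicate TSS peak. Of 1092 olfactory receptors only Olfr94 was marked, against a matched median of 82 (adjusted p = 0.001 by permutation), while replicate 1 marked 17 and replicate 2 marked 10. Macrophage genes were marked in 2 of 20 cases, Cd14 and Fcer1g, with 4 in each replicate, and heart muscle genes in 6 of 20. Both lists differed from other genes by Fisher's exact test (adjusted p = 4.1e-06 and 0.0075) but did not pass the test against matched lists (adjusted p = 0.658 and 0.243 by permutation), and the heart muscle list did not pass Fisher's test with the pooled list (adjusted p = 0.190). Where another gene's TSS lay within 2000 bp, a peak could not be assigned to either gene. None of the 22 hepatocyte genes without such a neighbour was marked, and Foxa3 was not among them.

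For most lists of other cell types in the face, the share of marked genes did not pass the test for a difference from other genes. Oral and facial epithelium had 15 of 21 marked genes, including Pitx2, Esrp2 and Dsp, while the keratin genes Krt14, Krt15 and Krt19 were unmarked in the replicated list. Krt19 had a TSS peak in replicate 2, and the keratin genes Krt8 and Krt18, chosen after their values were seen, were marked in both replicates and in the replicated list. Cartilage and bone had 13 of 20, among them Col2a1, Sox9 and Sox6, which act in cartilage, and Bglap, Col10a1 and Dmp1 were unmarked. Skeletal muscle had 9 of 20. Among its members the myosin light chain gene Mylpf (3568 bp) and the transcription factor genes Pax7 and Msc were marked, and the actin genes Acta1 and Actc1 and the receptor gene Chrna1 were unmarked, with a TSS peak at Acta1 in replicate 2. Neural crest glia and melanocytes had 7 of 12, with Erbb3, Sox10 and the melanocyte gene Pmel marked. Dct, Fabp7 and Foxd3 were unmarked, with a TSS peak at Fabp7 in replicate 1 and at Foxd3 in replicate 2. Endothelium had 8 of 20, with Prox1, Egfl7 and Erg marked and Emcn, Cdh5 and Esam unmarked, the last 2 with a TSS peak in replicate 1 and in replicate 2, respectively. Erythroid cells had 9 of 21, with Tal1, Klf1 and Tfrc marked and Alas2, Gata1 and Hba-a1 unmarked. For none of these 6 lists was the adjusted p below 0.05, by Fisher's exact test or by permutation. By Fisher's exact test, skeletal muscle genes were marked less often with a −log10 q of at least 5 (adjusted p = 0.00377), erythroid genes with a TSS window of 500 bp (adjusted p = 0.0187) and endothelial genes with only the most upstream TSS (adjusted p = 0.0354). These calls rest on Fisher's test alone, since matched lists were not drawn under those settings. In the main setting the matched medians were 8 for skeletal muscle, 7 for erythroid cells and 12 for endothelium, so only endothelium lay below its median. Neurons had 18 of 20 marked genes, with Isl1, Gap43 and Ascl1 among them and Dcx and Phox2b unmarked. The adjusted p was 0.017 by Fisher's exact test in the replicated list, 0.0952 in replicate 1, 0.138 in replicate 2 and 0.227 against matched lists. Ribosomal proteins were marked in 78 of 81 cases (adjusted p = 1.3e-11 by Fisher's exact test), and the unmarked members were Rpl10l, Rpl39l and Rpl3l, the last with a TSS peak in replicate 1. Matched lists had a median of 75 (adjusted p = 0.226 by permutation).

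**Figure D2:**
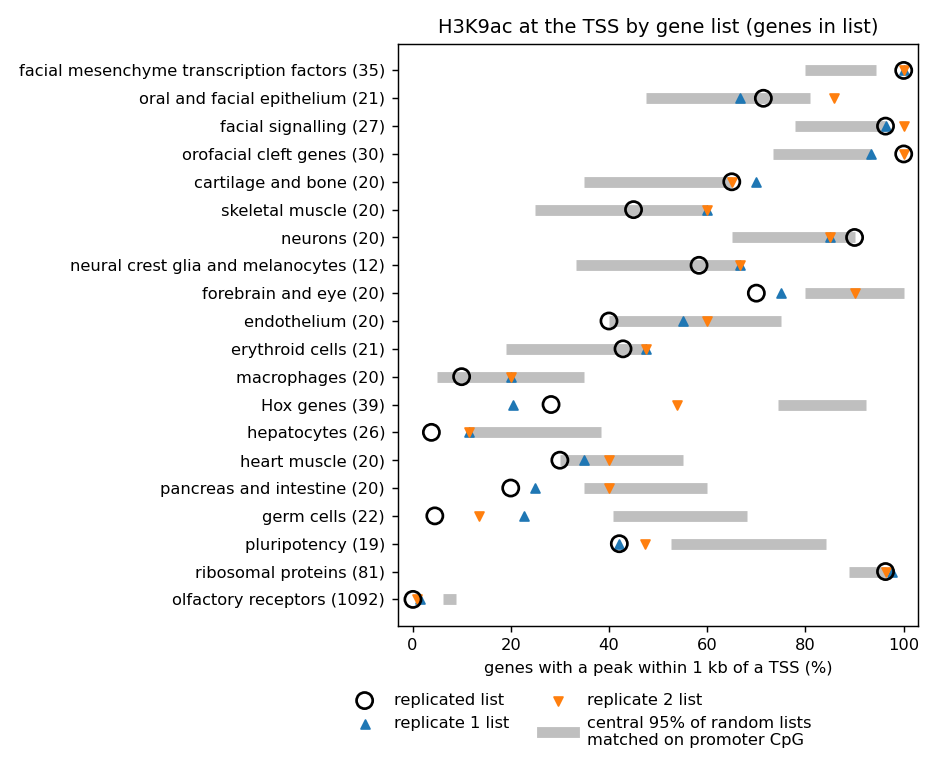
Share of genes with a peak within 1 kb of a TSS (x axis, percent) for the 20 gene lists (y axis, number of genes in parentheses). Open circles are the replicated list, upward triangles replicate 1, downward triangles replicate 2, and grey bars the central 95% of 10000 random lists matched on promoter CpG. Facial mesenchyme factors and cleft genes lie above their bars, and Hox genes, at 28.2%, lie below theirs.

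Hox genes, which set position along the body axis behind the face, were marked in 11 of 39 cases although their promoters are rich in CpG. Matched lists had a median of 32 (adjusted p = 0.001 by permutation, and 3.9e-05 by Fisher's exact test). The widest coverage was at Hoxa2, with 6906 bp (4554 in replicate 1 and 6007 in replicate 2), and then at Hoxa1 and Hoxb2, with 2343 and 2215 bp. The domain at the start of Hoxa1 itself was 435 bp wide, and its window of 5000 bp reached into the domain of Hoxa2, which began at 52160328 on chromosome 6. Hoxb2 had no TSS peak in replicate 1, where 405 bp were covered, against 2318 bp in replicate 2. Hoxa10, Hoxa11 and Hoxa13 were unmarked, with a TSS peak at Hoxa10 in replicate 2. The count differed between the replicates, with 8 marked genes in replicate 1 and 21 in replicate 2, where Fisher's test no longer passed (adjusted p = 0.158). Forebrain and eye genes were marked in 14 of 20 cases, below a matched median of 18 (adjusted p = 0.028 by permutation), but did not pass Fisher's exact test against other genes (adjusted p = 0.717). Six3, Emx2 and Lhx2 were marked, and Gsx2, Lhx5 and Nkx2-1 were not, although Gsx2 had a TSS peak in replicate 2 and Nkx2-1 in replicate 1. Replicate 1 marked 15 of these genes and replicate 2 marked 18, and with the pooled list they were marked more often than other genes (adjusted p = 0.0140 by Fisher's exact test). Pluripotency genes were marked in 8 of 19 cases against a matched median of 13 (adjusted p = 0.017 by permutation, 0.124 by Fisher's exact test). Klf4, Sox2 and Sall4, which also act outside pluripotent cells, were marked, and Dppa2, Dppa4 and Dppa5a were not.

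Among the 20 lists, the mark was widest at the transcription factors of facial mesenchyme. Their median width was 6253 bp within 5000 bp of a TSS, against 1617 bp in matched lists, whose central 95% ran from 1259 to 2011 bp. The medians were 5149 bp in replicate 1 and 6123 bp in replicate 2. Six2 had 9836 bp (9203 in replicate 1 and 9733 in replicate 2), Lhx8 9263 bp (7496 and 8664) and Satb2 8516 bp (7046 and 8135). Orofacial cleft genes had a median of 4080 bp against 1518 bp, with 8349 bp at Pax9 and 8204 bp at Msx1. Facial signalling genes had 3433 bp against 1548 bp, with 8836 bp at Wnt5a, 8163 bp at Pdgfra and 7134 bp at Ptch1. Ribosomal protein genes had 2530 bp against 1811 bp, the highest being Rpl18 with 5607 bp, of which its own domain made up at most 3122 bp. Hox genes had a median of 0 bp against 1448 bp, and of 0 bp in replicate 1 and 265 bp in replicate 2. The adjusted permutation p of these 5 lists was 0.0008 in the replicated list and in each replicate, and their unadjusted p in the replicated list was 0.0002, the smallest that 10000 random lists can give. For the other 15 lists the adjusted p was above 0.05 in the replicated list. Pluripotency genes had an adjusted p of 0.0587 there, and of 0.0400 and 0.0307 in replicates 1 and 2. The call of Hox genes was lost against lists not matched on CpG (adjusted p = 0.145 by permutation).

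**Figure D3:**
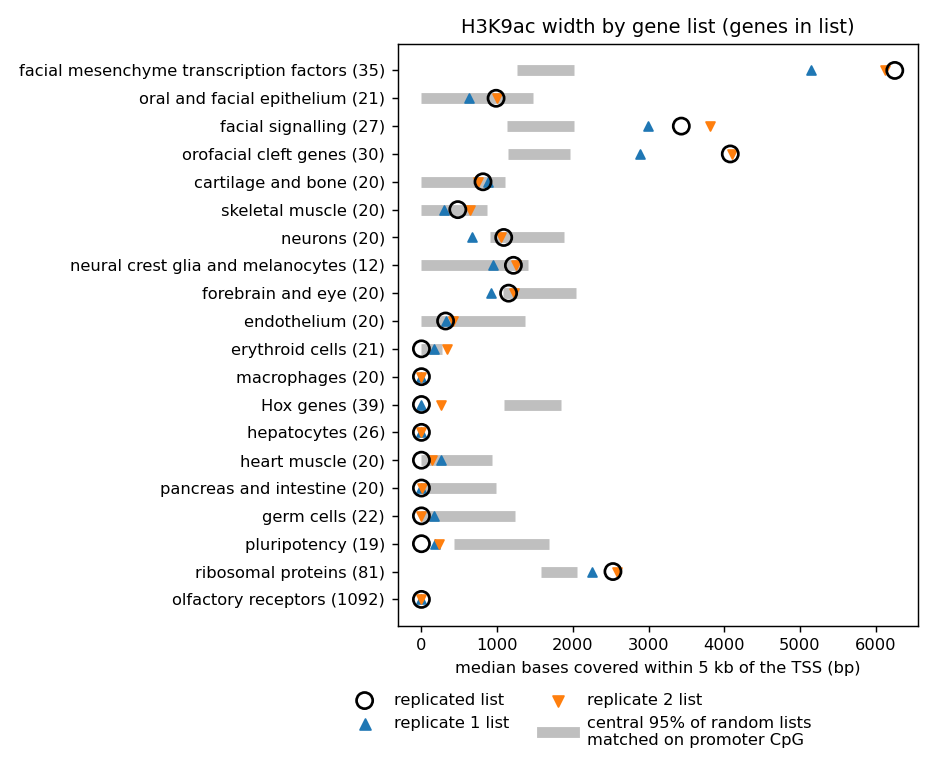
Median bases covered by peaks within 5 kb of the TSS (x axis, bp) for the 20 gene lists (y axis, number of genes in parentheses). Open circles are the replicated list, upward triangles replicate 1, downward triangles replicate 2, and grey bars the central 95% of 10000 random lists matched on promoter CpG. Facial mesenchyme factors, at 6253 bp, lie farthest to the right of their bar.

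With peaks merged within 1000 bp, the widest domain at a TSS spanned Nr2f2, which encodes an orphan nuclear receptor, with 21243 bp at chromosome 7, 70345959 to 70367201, covering the gene and sequence beyond its 3′ end. Ebf3 followed with 19592 bp (chromosome 7, 137303635 to 137323226). Next were the T-box genes Tbx3 with 17843 bp (chromosome 5, 119665728 to 119683570) and Tbx2 with 16079 bp (chromosome 11, 85829152 to 85845230). Bahcc1 had 15970 bp, the homeobox gene Meis2 15834 bp, the orphan receptor gene Nr2f1 15483 bp and Tnrc18 15020 bp. A domain of 14506 bp on chromosome 7, 127013982 to 127028487, held the starts of Gm42742, Maz, Mvp, Pagr1a, Pagr1b and Prrt2, and so counts 6 times among the 20. Mn1 had 14284 bp, Zmynd8 14101 bp and the histone demethylase gene Kdm6b 13790 bp. Lrba and Mab21l2, a gene that lies inside Lrba, shared 13527 bp. Twist1, a basic helix-loop-helix factor of cranial mesenchyme, had 13435 bp on chromosome 12, 33955701 to 33969135, from upstream of the gene (33957671 to 33959829) to downstream of its 3′ end. In the list of replicate 2 alone, 13 of these 20 genes were among the widest 20, and in that of replicate 1 alone, 11. Merging within 0 bp or within 3000 bp left 7 of the 20 in each case. The widths themselves depended on merging: within 0 bp Tbx2 kept its 16079 bp and the other 19 moved, to 7335 bp at Nr2f2, 7366 bp at Ebf3 and 2003 bp at Twist1. Within 3000 bp Bahcc1 had 27275 bp and Nr2f2 24748 bp. In replicate 1 the domain was 11433 bp at Ebf3, 7815 bp at Lrba and Mab21l2 and 4168 bp at Zmynd8, and with a −log10 q of at least 5 it was 10849 bp at Ebf3, 8359 bp at Kdm6b and 8461 bp at Twist1. The 6 genes of the shared domain had between 5171 and 8018 bp (Maz and Mvp) in single replicates.

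**Figure D4:**
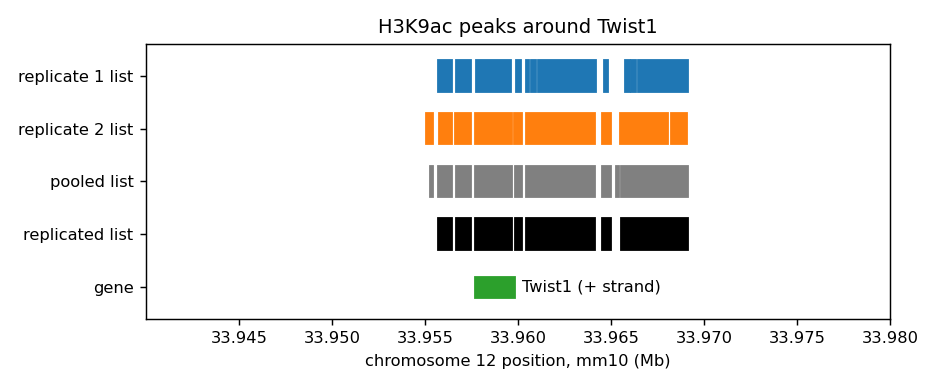
Peaks of the 4 lists around Twist1 on chromosome 12 (x axis, mm10 position in Mb), with 1 row per list (y axis) and the gene in green. The replicated peaks run from 33955701 to 33969135, and both replicates have peaks over most of that stretch.

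Among the 20 lists, the transcription factors of facial mesenchyme had the highest mean number of distal peaks in the replicated list and in each replicate. In the pooled list ribosomal protein genes had more, with a mean of 12.95 against 12.4. Of the replicated peaks, 8783, or 29.7%, lay over 2500 bp from any TSS, against 53.6% of the peaks of replicate 1 and 56.3% of those of replicate 2. Transcription factors of facial mesenchyme had a mean of 4.34 of them within 100000 bp, against 0.886 in lists matched on gene density (adjusted p = 0.002 by permutation), and of 9.77 in replicate 1 and 12.03 in replicate 2. By the same permutation test, cleft genes had 2.83 against 1.00 (adjusted p = 0.0067), facial signalling genes 2.07 against 0.852 (adjusted p = 0.033) and ribosomal protein genes 2.70 against 1.83 (adjusted p = 0.033). Hox genes had fewer, 1.44 against 2.69 (adjusted p = 0.033 by permutation), and olfactory receptors 0.168 against 2.29 (adjusted p = 0.002 by permutation). Genes of these 2 lists lie in clusters and share distal peaks within 100000 bp, while the random lists are scattered, so these p-values may be too small. Other lists can also hold neighbouring genes that share distal peaks, such as Rps11 and Rpl13a among ribosomal protein genes. The p-values of those lists may be too small for the same reason. The means were higher in replicates 1 and 2, with 8.13 and 9.47 for cleft genes, 6.04 and 8.26 for facial signalling, 8.63 and 11.31 for ribosomal protein, 4.26 and 4.64 for Hox genes and 0.672 and 0.534 for olfactory receptors. For the other 14 lists the adjusted p was above 0.05 in the replicated list. Cartilage and bone genes passed in replicate 2 (adjusted p = 0.0326 by permutation) but not in replicate 1 (0.0520). Width was counted to 5000 bp from a TSS and distal peaks began at 2500 bp, so outer peaks of a wide domain could count in both. The distal counts are therefore not separate from the width results. For distal peaks over 10000 bp from a TSS the adjusted p of mesenchymal factors and of cleft genes became 0.0587 by permutation, with means of 1.37 and 1.27, and the calls of facial signalling, Hox and ribosomal protein genes were lost. The call of facial signalling genes was also lost in replicate 1 (adjusted p = 0.0520 by permutation, against 0.0153 in replicate 2), with the pooled list (0.0503), with a −log10 q of at least 5 (0.176) and within 250000 bp (0.141). That of ribosomal protein genes was lost with a −log10 q of at least 5 (adjusted p = 0.2005 by permutation), and that of Hox genes within 50000 bp (0.411). Against lists not matched on gene density the adjusted permutation p was 0.133 for cleft genes, 0.562 for facial signalling and 0.882 for Hox genes. The genes with the most distal peaks were Sept9, with 31, then 1600002K03Rik and Ndufs7, with 25 each, and Ahdc1, Cirbp, Efna2, Midn and Src, with 24 each. Mum1 had 23 and Atp5d 22. These counts were higher in the lists of single replicates, with 52 and 79 at Sept9 in replicates 1 and 2, and 35 to 45 and 48 to 52 at the other 9 genes. Of these, 1600002K03Rik, Ndufs7, Cirbp, Efna2, Midn, Mum1 and Atp5d lie together on chromosome 10, 80138632 to 80256794, and share peaks. The windows of all TSSs of a gene were counted together, so a gene with TSSs far apart was searched over more sequence. This ranking was not adjusted for that.

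Sites for the transcription factor TFAP2 and for CTCF were more frequent in distal peaks than in flanking sequence, and 6 other motifs were less frequent. The TFAP2 site GCCNNNGGC was in 24.6% of 8780 peak windows and 11.6% of 11763 flanking windows (odds ratio 2.47, 95% interval 2.29 to 2.66). The site of the insulator protein CTCF was in 1.36% and 0.425% (odds ratio 3.22, 2.31 to 4.48), with an odds ratio of 2.05 in replicate 1 and 2.00 in replicate 2. The homeodomain site TAATTA was in 6.45% and 11.5% (odds ratio 0.532, 0.480 to 0.589), and the TWIST-type E-box CAGATG in 32.4% and 36.6% (odds ratio 0.830). Adjusted p by Fisher's exact test was at most 0.027 for 8 of the 9 motifs, and 0.070 for the E-box and homeodomain pair, whose sites lay within 20 bp of each other. The pair was less frequent in peaks of replicate 1 (adjusted p = 0.0461 by Fisher's exact test) and of replicate 2 (0.000568). The peak windows held 53.8% GC and the flanks 46.7%. Matching on GC kept only a part of the peaks, with 5391 windows of peaks and of flanks at 49.8% and 49.7% GC. The TFAP2 site was in 16.5% of these peaks and 16.3% of these flanks. With flanks matched on GC in this way, the TFAP2 odds ratio was 1.01 (adjusted p = 0.894 by Fisher's exact test) and that of the homeodomain site 0.906 (adjusted p = 0.221). The SOX site turned from 0.903 to 1.28 (adjusted p = 0.00022 by Fisher's exact test) and the forkhead site from 0.846 to 1.24 (adjusted p = 0.020). The E-box CAGATG had an odds ratio of 0.999 in replicate 1 and 1.01 in replicate 2, and the SNAI/ZEB E-box went from 0.876 to 1.02 and 1.04. With flanks matched on GC these 2 E-boxes stayed less frequent, with odds ratios of 0.790 and 0.580 (adjusted p = 3.1e-08 and 9.2e-40 by Fisher's exact test). CTCF had an odds ratio of 2.18 (adjusted p = 0.00072 by Fisher's exact test) with GC-matched flanks, but in windows of 100 bp to either side it was 0.503 (adjusted p = 0.066 by Fisher's exact test).

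Chromosome X carried fewer peaks than the autosomes. It held 3.96 replicated peaks per Mb against 12.1 on the autosomes, a ratio of 0.328. The ratio was 0.217 in replicate 1, 0.191 in replicate 2 and 0.173 in the pooled list. Of its 948 protein-coding genes 44.3% were marked, against 64.2% of 20780 autosomal genes (odds ratio 0.443, p = 4.0e-34 by two-sided Fisher's exact test). Replicate 1 gave 45.1% against 65.8% and replicate 2 gave 46.4% against 67.7%. Chromosome 11 had the highest density, with 22.02 replicated peaks per Mb, and 48.9 and 58.0 in replicates 1 and 2. Chromosome Y had the lowest, with 4 replicated peaks, and 10 and 4 peaks in replicates 1 and 2.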

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

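The replicated list held 11 peaks on sequences outside chromosomes 1 to 19, X and Y, which no comparison above used, with a median fold of 4.80 against 4.97 on the chromosomes. The list of replicate 1 held 32 such peaks, that of replicate 2 held 9 and the pooled list 20. There is no control sample to set them against, and their source was not tested.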

How the results depend on the processing

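The comprehensive annotation, genes without another TSS nearby and lists matched on the number of CpGs were chosen only after the results were seen. No paired analysis was possible because there is 1 group. Of the values recomputed for lists, motifs, overlap and location, those below changed direction, passed or missed the threshold, or moved by more than the spread between replicates, and the cause was not tested. Of 50 turned values, those past the threshold were forebrain and eye genes against CpG-matched lists, epithelial width against lists matched on the number of CpGs, the SNAI/ZEB E-box in replicate 2, and the SOX and forkhead sites with GC-matched flanks. The values that kept direction and call numbered 168 for marked lists, 150 for width, 131 for distal peaks and 45 for motifs. At single named genes, 127 values of bases covered moved by more than the spread and 285 did not. For domain widths these numbers were 58 and 62, and for counts of distal peaks 38 and 2. The spread was the SD of the 2 single-replicate values, and those values are themselves among the alternatives. A gene with 0 bp in every list counts as not moved. These numbers are therefore not a measure of how stable the values are. The width of mesenchymal factors, cleft genes, facial signalling genes and ribosomal proteins kept both under every alternative. The count of marked genes stayed within 1.5 times under all 8 alternatives, and the X odds ratio kept its direction and call under all 4. Single replicate lists are longer and hold weaker peaks than the replicated list, so they differ in more than 1 replicate left out. Depth is unknown, which limits any statement on a peak missing from 1 list.

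Overlap of the replicates was 27.8% and 24.9% by at least 0.5 of both peaks, and 89.4% and 75.5% with a −log10 q of at least 5, where the shared bases rose to 0.664. Replicated peaks met by both replicates fell to 61.0% by 0.5 of both peaks. The share of peaks at a TSS ranged from 32.5% to 35.7% over single replicates, and was 31.5% in the pooled list, 74.6% with a −log10 q of at least 5, 57.1% and 70.3% with windows of 500 and 2500 bp, and 66.7% with the comprehensive annotation. Of the 20 widest genes, 11 to 13 stayed with single replicates, 13 with the pooled list and 7 with merging at 0 bp or 3000 bp.

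For the share of marked genes over that expected: Calls were lost with the pooled list (neurons 1.35, heart muscle 0.749), with a −log10 q of at least 5 (neurons 1.23) and with a TSS window of 500 bp (neurons 1.29). This also held with the most upstream TSS alone (neurons 1.39) and against CpG-matched lists (facial signalling 1.08, neurons 1.12, macrophages 0.667, heart muscle 0.75, ribosomal proteins 1.04). Calls were gained with the pooled list (forebrain and eye 1.42), with a −log10 q of at least 5 (skeletal muscle 0.41, pluripotency 0.518) and with a TSS window of 500 bp (erythroid cells 0.537). This also held with the most upstream TSS alone (endothelium 0.573) and against CpG-matched lists (pluripotency 0.615). Except against CpG-matched lists, these calls are by Fisher's exact test alone. The direction turned with a −log10 q of at least 5 (cartilage and bone 0.984, forebrain and eye 0.82), with a TSS window of 500 bp (epithelium 0.843, cartilage and bone 0.966) and with a TSS window of 2500 bp (glia and melanocytes 1.04). This also held with the most upstream TSS alone (forebrain and eye 0.983) and against CpG-matched lists (skeletal muscle 1.12, glia and melanocytes 1.17, forebrain and eye 0.778, erythroid cells 1.29). Over the lists of single replicates the changed values ranged as follows: cartilage and bone 0.982 to 1.09, neurons 1.28 to 1.32, glia and melanocytes 1.01 to 1.04, Hox genes 0.318 to 0.813.

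For the median width (bp): Calls were lost against unmatched lists (Hox genes 0). Calls were gained with the pooled list (pluripotency 277), with a −log10 q of at least 5 (forebrain and eye 758) and within 2500 bp (forebrain and eye 678). This also held against unmatched lists (olfactory receptors 0) and against lists matched on the number of CpGs (neurons 1087, forebrain and eye 1152, endothelium 319, heart muscle 0, germ cells 0, pluripotency 0). The direction turned with the pooled list (macrophages 86.5, heart muscle 486), with a −log10 q of at least 5 (skeletal muscle 0) and within 2500 bp (epithelium 752). This also held within 10000 bp (erythroid cells 208), against unmatched lists (epithelium 986, cartilage and bone 814, skeletal muscle 480, neurons 1087, forebrain and eye 1152) and against lists matched on the number of CpGs (epithelium 986, cartilage and bone 814, skeletal muscle 480). Over the lists of single replicates the changed values ranged as follows: epithelium 623 to 992, erythroid cells 171 to 343, heart muscle 144 to 260, pluripotency 177 to 237.

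For the mean number of distal peaks: Calls were lost with the pooled list (facial signalling 8), with a −log10 q of at least 5 (facial signalling 0.926, ribosomal proteins 1.21) and over 10000 bp from a TSS (mesenchymal factors 1.37, facial signalling 1.04, cleft genes 1.27, Hox genes 0.231, ribosomal proteins 0.877). This also held within 50000 bp (Hox genes 1.03), within 250000 bp (facial signalling 3.52) and against unmatched lists (facial signalling 2.07, cleft genes 2.83, Hox genes 1.44). Calls were gained with the pooled list (cartilage and bone 12.3). The direction turned with the pooled list (germ cells 7.68, pluripotency 7.21), with a −log10 q of at least 5 (macrophages 0.8, germ cells 0.773) and over 10000 bp from a TSS (pluripotency 0.579). This also held within 50000 bp (erythroid cells 0.952) and within 250000 bp (erythroid cells 4.9, pluripotency 3.47). Over the lists of single replicates the changed values ranged as follows: facial signalling 6.04 to 8.26, cartilage and bone 7.8 to 10.2, glia and melanocytes 4.17 to 6.5, germ cells 6.18 to 7.27, pluripotency 5.21 to 6.74.

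For the motif odds ratio: Calls were lost with the pooled list (TWIST-type E-box 0.995, SNAI/ZEB E-box 0.991), in windows of 100 bp (SNAI/ZEB E-box 0.945, forkhead 0.821) and in windows of 500 bp (SNAI/ZEB E-box 0.949). This also held with GC-matched flanks (homeodomain 0.906, TFAP2 1.01). Calls were gained in windows of 100 bp (E-box and homeodomain 0.284). The direction turned in windows of 100 bp (CTCF 0.503) and with GC-matched flanks (E-box and homeodomain 1.08, SOX 1.28, forkhead 1.24). Over the lists of single replicates the changed values ranged as follows: TWIST-type E-box 0.999 to 1.01, E-box and homeodomain 0.664 to 0.774, SNAI/ZEB E-box 1.02 to 1.04.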

Other observations

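The tests of gene families, Hox groups, the sensitivity of replicate 2, lists matched on the number of CpGs and genes without a nearby TSS were chosen only after the data were seen. Of 252 families of at least 10 protein-coding genes that share the stem of their symbol, 5 were wider and 5 narrower than lists matched on promoter CpG at an adjusted permutation p below 0.05. By the same threshold, 5 families were marked more often than matched lists and 14 less often. The frizzled receptors of the Wnt pathway (Fzd) were marked in 10 of 10 cases, as in the median of matched lists, with a median width of 3676 bp against 1936 bp in matched lists (adjusted p = 0.010 by permutation). The Arid family had 3486 bp against 1743 bp (adjusted p = 0.014 by permutation). Semaphorins (Sema), which act in axon and cell guidance, had 2292 bp against 1326 bp, and collagens (Col) 1538 bp against 845 bp (adjusted p = 0.039 by permutation for both). Both were also marked more often than matched lists. Sema had 20 of 20 marked genes against a matched median of 15 (adjusted p = 0.011 by permutation). Col had 37 of 45 against 27 (adjusted p = 0.0039 by permutation), a call lost in replicate 1 (0.0711). Histone genes (Hist) had 3006 bp against 1985 bp (adjusted p = 0.010 by permutation), and they lie in clusters, where the window of 1 gene holds the peaks of others. Of the histone genes 57 of 67 were marked, against a matched median of 65 (adjusted p = 0.0039 by permutation), although Fisher's exact test put them above other genes.

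Among the clustered protocadherins, cell surface proteins of neurons, none of the 11 Pcdha, 22 Pcdhb and 12 Pcdhga genes had a replicated TSS peak (adjusted p = 8.4e-05, 5.4e-09 and 3.4e-05 by Fisher's exact test over the families). Matched lists had a median of 10 marked genes for each of the 3 (adjusted p = 0.0039 by permutation for each). The clustered genes Pcdhac2, Pcdhgc3 and Pcdhgc4, chosen after their values were seen, were marked in both replicates and in the replicated list. The narrower families were Pcdha and Pcdhga, both with a median width of 0 bp, against 1564 and 1327 bp, Hoxa with 229 bp against 1543 bp (adjusted p = 0.010 by permutation for the 3), the ubiquitin ligase genes March with 846 bp against 1800 bp (adjusted p = 0.040 by permutation) and Nkx. In the list of replicate 2, 3 Pcdhga genes had a TSS peak, and in that of replicate 1 none did. Of the Nkx genes, homeobox factors of many organs, 6 of 14 were marked (8 in replicate 1 and 9 in replicate 2), with a median width of 469 bp against 1495 bp (adjusted p = 0.014 by permutation). The matched median was 12 marked Nkx genes (adjusted p = 0.0039 by permutation), a call lost in replicate 1 (0.0728) and in replicate 2 (0.222). Keratin genes (Krt) were marked in 4 of 53 cases, with 10 in replicate 1 and 11 in replicate 2 (adjusted p = 1.9e-15 by Fisher's exact test). Matched lists had a median of 21 (adjusted p = 0.0039 by permutation), and neither their width nor that of Pcdhb genes passed the test against matched lists. In Hox paralogue groups 1 to 4, 7 of 12 genes had a replicated TSS peak, and in groups 5 to 13, 4 of 27. Replicate 1 gave 5 of 12 and 3 of 27, and replicate 2 gave 8 of 12 and 13 of 27, and the difference between the groups was not tested.

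The wide mark at transcription factors of facial mesenchyme was set against 2 technical explanations. The tables argue against long CpG-rich sequence as the whole cause, within a limit. Against lists matched on the number of CpGs within 5000 bp of the most upstream TSS, the median of 6253 bp lay at percentile 100. The central 95% of those lists ran from 1945 to 3039 bp. Width was taken at the TSS with the most bases covered, so in genes with several TSSs the CpGs counted can lie elsewhere. The tables argue in the same way against peaks of neighbouring genes. The 14 members with no other gene's TSS within 10000 bp had a median of 5109 bp. This was again at percentile 100, with matched lists between 910 and 1835 bp. Stronger signal in general, which would widen all peaks at highly transcribed genes, was not tested. No biological explanation was tested, because the design has 1 group.

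More Hox genes had a TSS peak in replicate 2 (21) than in replicate 1 (8), and a higher sensitivity of the list of replicate 2 may account for this. Of 15 Hox genes marked in a single replicate, 14, or 93.3%, were in replicate 2 only. Over all protein-coding genes this share was 66.8%, and in genes matched on promoter CpG its central 95% ran from 53.3% to 93.3%, so the Hox value lay on the upper bound (p = 0.116 by permutation). The fold of their peaks leaves this open, since the median of 3.08 over the 14 genes was below the 25th percentile over all marked genes of that list (6.16), but the 796 protein-coding genes in replicate 2 only also had a median of 3.08. A difference in the tissue taken into the pools was not tested and stays open.

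Fewer marked genes on chromosome X are not accounted for by CpG-poor promoters alone. Stratified on 10 bins of promoter CpG, the odds ratio was 0.475, with a 95% interval of 0.391 to 0.576. A candidate explanation is that each cell has 1 active X, against 2 active copies of each autosome. Among marked genes matched on promoter CpG, the median TSS fold on X was 0.688 of that on the autosomes, below random autosomal lists (0.931 to 1.08), and 0.746 in replicate 1 and 0.754 in replicate 2. These folds cover only marked genes, so they do not test why fewer genes on X were marked. Whether the kinds of genes on X play a part was not tested. The fold is taken over a control whose own coverage of X was not analysed here, so copy number in male embryos and mapping to repeats on X stay open.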
